A study of Mus musculus with 7 samples.

How the data were processed

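RNA was measured in 7 libraries, 4 from DSS-treated and 3 from water-treated mice. The labels do not state outright that each library is a separate animal, so p-values measure the spread between these samples. No pair of libraries matched within sampling noise (chi-square per degree of freedom of at least 13.3). Per the labels' protocols, crypts were freed from the small intestine with EDTA and dissociated, and live single cells were sorted by CD24 and side scatter. Cells positive for TER119, CD31 or CD45, which mark red, endothelial and white blood cells, were excluded, and CD117, the Kit protein, was stained as well. Mice were 12, 12 and 10 weeks old in water 1 to 3 and 12, 10, 10 and 10 weeks old in DSS 1 to 4. RNA was isolated on days 14, 14 and 21 of November for the water mice and on days 9, 16, 16 and 24 for the DSS mice. Replicates were numbered within each group in accession order, so the numbers pair nothing. The titles of water 3, DSS 2 and DSS 3 share the number 19083, whose meaning the labels do not give.

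The deposited files hold raw counts per gene for 52550 genes, made with featureCounts 1.5.3 per the file headers. The submitters' processing notes name STAR 2.5.3a, featureCounts 1.5.2, DESeq2 and the build mm10. Per the file headers, exons were counted by gene with primary alignments only, a minimum overlap fraction of 0.8 and no strand option. Reads of overlapping or antisense genes can therefore not be told apart, and the primary alignments of reads with several matches are included, which matters for alpha-defensins and ribosomal protein genes. Gene symbols came from GENCODE release 21, matched by identifier for 52403 genes, with 147 unmatched. Total counts ran from 23175708 to 32451653, at which 3 counts correspond to between 0.0924 and 0.129 CPM. Intervals on shares cover counting error only.

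The main comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr left 17449 genes, TMM factors scaled the libraries, and the quasi-likelihood test compared DSS with water with no covariate. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 changes are DSS relative to water with the standard error from the fit, and CPM values are TMM-normalised. TMM factors ran from 0.899 to 0.922 in water and from 0.980 to 1.14 in DSS. DESeq2 1.42.0 and limma 3.58.1 served as alternatives. Single values per library were compared by exact permutation over all 35 splits, two-sided.

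Before the data were examined, 37 gene lists, the tests, the alternatives and the rule for named genes were fixed, and 34 lists had at least 5 tested members. The lists of neutrophil, mesenchymal and erythroid markers had 3, 4 and 2 tested members and were not tested. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 34 lists, and beside it with an estimated correlation and with fry, a rotation test. Members were also adjusted over the list alone. The rule named 16 genes in any case, among them Kit, Lyz1 and Lgr5. It then took the 12 largest rises and falls past the threshold, with an average log2 CPM of at least 3 and no overlap between groups. Where fewer than 5 passed in a direction, it took the 5 smallest p-values there. In both cases it left out symbols of predicted or unnamed genes, pseudogenes and clone accessions. From each list described it took up to 4 members with the smallest p, of which 1 is not reported here.

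The alternatives were other size factors, library totals only, scaling without granule genes, DESeq2, limma-voom with quality weights, a test against a fold of 1.5, no low-count filter, a filter of 1 CPM in 4 libraries, age as a covariate, lane 6 libraries only, 10-week mice only and leaving out each replicate. Leaving out DSS 2 with DSS 3, robust dispersions, the permutation of list means and the estimated correlation without single libraries were added after seeing the data. The steps were tested on simulated data drawn from these libraries' means, totals and dispersions over 17449 genes. There, edgeR recovered 52.2% of 67 genes changed by 1.5-fold, 88.1% of 67 changed by 2-fold and 97.0% of 66 changed by 4-fold, and called 15 unchanged genes. DESeq2 recovered 68.7% of the genes changed by 1.5-fold and called 46 unchanged genes. The changed genes were drawn from those above 2 CPM, and genes were simulated independently with no library set apart. The recovered shares need therefore not hold for the real libraries.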

Results

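Paneth cells are the granule-filled secretory cells at the base of small-intestinal crypts. They release lysozyme and alpha-defensins and lie next to the Lgr5-positive stem cells. The 7 libraries measured polyadenylated RNA from sorted Paneth cells of Lgr5-EGFP-IRES-CreERT2 mice on a C57BL/6J background. The 4 DSS libraries came from mice that drank 3% dextran sulfate sodium, a polymer that injures the gut epithelium, for 7 days and were killed 3 days after its removal. The 3 control libraries came from mice kept on water. Total counts were 24504251, 23175708 and 25894328 in water 1 to 3, and 23179147, 32451653, 25480805 and 29360899 in DSS 1 to 4. The comparison of DSS with water addresses how Paneth cells respond to gut inflammation and whether they take up stem-like features, with attention to the receptor Kit and its ligand.

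Of 38 tested Paneth antimicrobial and granule genes, 8 fell and 0 rose after DSS when p was adjusted over the list alone, with 32 of the 38 estimates below 0. The list had a camera adjusted p of 1.06e-16, or adjusted p = 0.297 with an estimated correlation, and an adjusted p of 0.243 by exact permutation of the list mean. Lyz1, encoding the Paneth cell lysozyme, fell from 103240 ± 4412 CPM in water (SD, n = 3) to 53078 ± 17964 CPM in DSS (SD, n = 4), a log2 change of -0.96 ± 0.27 (SE). Lyz2, a second lysozyme, changed by -0.99 ± 0.21, and the alpha-defensins Defa30 and Defa31 by -0.83 ± 0.21 and -0.74 ± 0.15. None of the 38 passed over all genes in edgeR. Mmp7, the protease that activates alpha-defensins, was at -0.26 ± 0.15 and Defa17 at -0.47 ± 0.21, and neither passed (adjusted p over the list alone of 0.152 and 0.118). Lyz1 with Lyz2, and the alpha-defensins among themselves, are near-identical copies between which reads can be split, so their separate values are uncertain.

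The share of all counts in these granule genes was 35.97% ± 0.990 in water (SD, n = 3) and 26.5% ± 4.50 in DSS (SD, n = 4), 9.48 percentage points lower. The DSS libraries lay at 32.4%, 27.7%, 22.7% and 23.3%, each below all 3 water libraries, and 95% Wilson intervals were within 0.0196 points of each share. The exact permutation test, two-sided over all 35 splits, gave p = 0.0571, against a smallest possible p of 0.0286. With 13 single values per library tested in this family, the Benjamini-Hochberg adjusted p was 0.0929. DSS 1 lay closest to water. The mean log2 level of the granule genes, relative to the water mean, was -0.07 in DSS 1, -0.26 in DSS 2, -0.78 in DSS 3 and -0.71 in DSS 4. Tuft cell markers, of another epithelial cell type, lay at -0.03, 0.75, 0.78 and -0.07 in the same libraries.

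**Figure D1:**
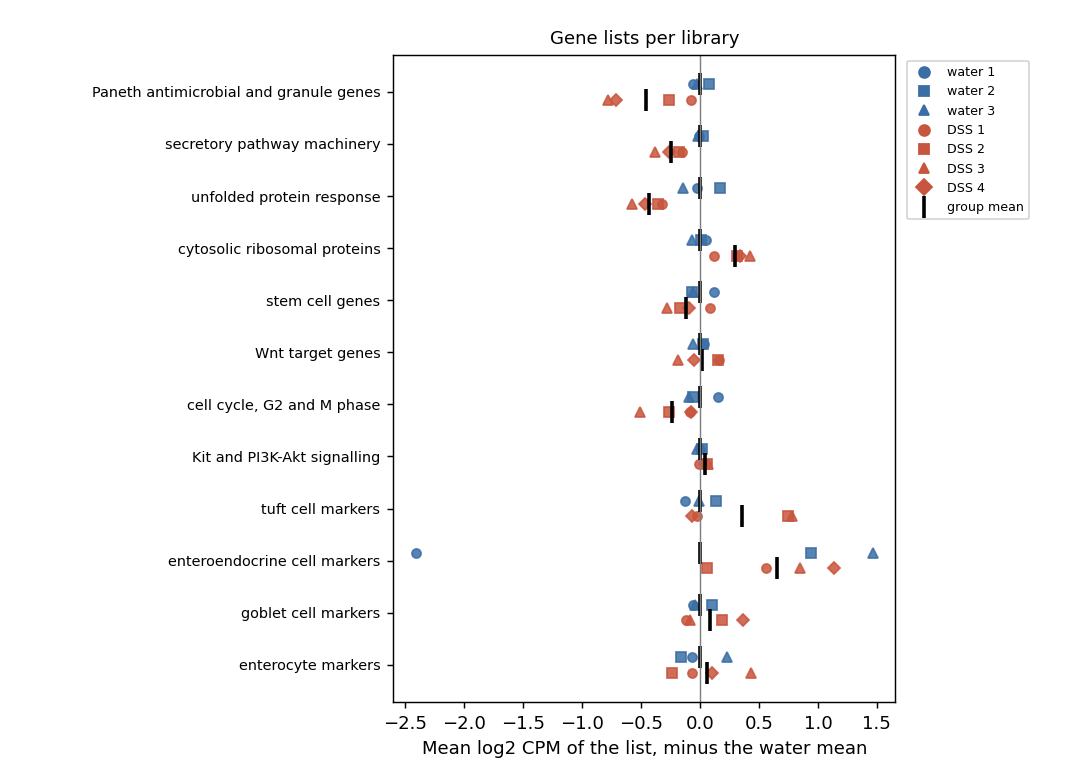
Mean log2 CPM of 12 gene lists in each of the 3 water (blue) and 4 DSS (red) libraries, minus the water mean, with black bars for group means. The granule genes lay at -0.07, -0.26, -0.78 and -0.71 in DSS 1 to DSS 4, and the enteroendocrine markers at -2.41 in water 1.

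Of 52 tested genes of the secretory pathway machinery, which move proteins into and through the endoplasmic reticulum and Golgi, 28 fell and 0 rose when adjusted over the list alone, and the camera adjusted p of 1.66e-22 became adjusted p = 0.297 with an estimated correlation. Among those that fell were Tmed2, a cargo receptor of early secretory vesicles (log2 change -0.37 ± 0.06), Spcs2, a signal peptidase subunit (-0.43 ± 0.08), and Srp54a, of the signal recognition particle (-0.38 ± 0.07). Of 35 genes of the unfolded protein response, 22 fell and 0 rose, adjusted over the list alone, and the camera adjusted p of 3.44e-21 became adjusted p = 0.245 with an estimated correlation. Manf, a secreted stress-induced factor, was 175 ± 1.46 CPM in water and 133 ± 4.98 CPM in DSS (SD, n = 3 and 4). The chaperone partners Dnajb11 and Dnajc3 changed by -0.38 ± 0.06 and -0.55 ± 0.10, and Xbp1, a transcription factor of this response, by -0.43 ± 0.10. The median log2 change was -0.32 in the unfolded protein response list and -0.23 in the secretory pathway machinery, which turned to 0.00055 with library totals only, where the median of all genes was 0.23.

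Of 82 tested genes for cytosolic ribosomal proteins, 71 rose and 1 fell when adjusted over the list alone, with a median log2 change of 0.30. The camera adjusted p of 4.94e-44 became adjusted p = 0.297 with an estimated correlation. Rpl23a was 45.6 ± 0.673 CPM in water and 65.8 ± 5.84 CPM in DSS (SD, n = 3 and 4), Rpl29 changed by 0.40 ± 0.07 and Rps19 by 0.46 ± 0.09. The member that fell, by 0.30, was Rps27l, which encodes a ribosomal-protein-like p53 target and was chosen here after its value was seen. Ribosomal protein genes share sequence with processed pseudogenes, between which reads can be split. Processed pseudogenes of any gene made up 120 of the 346 genes that DESeq2 called higher in DSS, or 34.7%, against 13.3% of the genes tested, and 35 of them had ribosomal protein symbols.

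These 4 lists passed the competitive test camera with its preset correlation of 0.01. With an estimated correlation none of the 34 lists passed, and these 4 had adjusted p = 0.297, adjusted p = 0.297, adjusted p = 0.245 and adjusted p = 0.297 in the order ribosomal proteins, secretory pathway, unfolded protein response and granule genes. By exact permutation of each list's mean over the 35 splits the adjusted p was 0.243 for each of the 4. The smallest p this test allows is 0.0286. The secretory pathway, the unfolded protein response and the type I interferon response were the 3 lists that reached it. After adjustment over 34 lists it could pass only if many lists reached that limit together, so its failure decides little. camera called 14 lists, and 17 of the 35 splits called at least as many.

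Kit and its ligand did not differ between the groups by more than the spread between libraries. Kit, the receptor tyrosine kinase, was 261 ± 12.3 CPM in water and 276 ± 28.8 CPM in DSS (SD, n = 3 and 4), a log2 change of 0.08 ± 0.09 with an edgeR adjusted p of 0.726. Its protein, CD117, was stained in the sort, so selection of cells by Kit level in both groups cannot be excluded. Kitl, which encodes stem cell factor, was at 0.07 ± 0.17 (adjusted p = 0.881). Of 48 genes of Kit and PI3K-Akt signalling 0 rose and 0 fell when adjusted over the list alone, and the list's camera adjusted p was 0.413. Cd24a, whose product was used for the sort, was at -0.23 ± 0.14, and 21 tested genes of Paneth specification and identity went both ways. Sox4, a transcription factor, rose by 0.44 ± 0.08, Fzd5, a Wnt receptor of Paneth cells, by 0.31 ± 0.08, and Kcnn4, a potassium channel, by 0.45 ± 0.12, while Xbp1 fell, all adjusted over the list alone. The 13 tested niche signals held 0 that rose and 0 that fell, with Wnt3 at -0.22 ± 0.16, Dll4 at 0.27 ± 0.16 and Egf at -0.36 ± 0.17.

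Stem cell genes went both ways. The list also stands for stem cells that the sort could have held. Its values therefore cannot tell changes within Paneth cells from a different number of stem cells in the sort. Of 41 tested, 6 rose and 3 fell when adjusted over the list alone, and the camera adjusted p was 0.843. Ascl2, a stem cell transcription factor, changed by 0.37 ± 0.11, Axin2, a Wnt target, by 0.28 ± 0.08, Ephb2 by 0.30 ± 0.08 and Kcnq1 by 0.48 ± 0.13. Sp5 and Mex3a rose by 0.42 and 0.38. Fam84a fell by 0.46, as did Clca4a by 0.97 and Fstl1 by 0.99 on the log2 scale, the last 2 chosen after their values were seen. Lgr5, the receptor that marks crypt base stem cells, was 127 ± 35.8 CPM in water and 78.5 ± 27.7 CPM in DSS (SD, n = 3 and 4). Its log2 change of -0.70 ± 0.26 did not pass (edgeR adjusted p = 0.247), and Olfm4 was at -0.06 ± 0.13. Of 28 Wnt targets 5 rose, with Myc at 0.35 ± 0.09 and Sp5 at 0.42 ± 0.11, and 2 fell, with Bambi at -0.84 ± 0.24 and Wif1, chosen after its value was seen, at -0.72 ± 0.22, adjusted over the list alone (camera adjusted p = 0.171). Sp5, Ephb2, Axin2 and Ascl2 are members of both the stem cell and the Wnt list, so the rises on these lists are not separate results. The median of the Wnt targets was 0.069, and 0.11 without DSS 3, where camera passed (adjusted p = 0.00798, or adjusted p = 0.588 with an estimated correlation). Of 25 reserve and injury-induced stem cell genes 3 rose and 0 fell, adjusted over the list alone, among them Krt19 at 0.49 ± 0.11 and Mex3a, while Clu, a marker of injury-induced stem cells, was low at 1.95 ± 0.229 CPM in water and 1.23 ± 0.511 CPM in DSS.

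**Figure D2:**
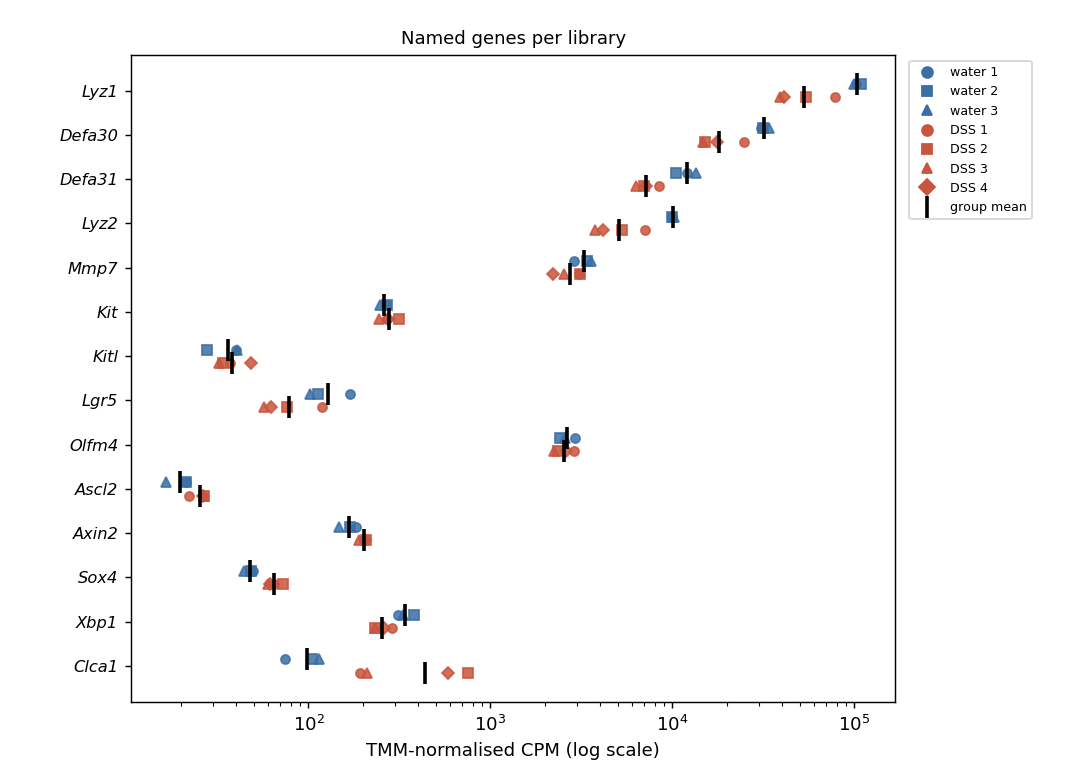
TMM-normalised CPM, on a log axis, of 14 named genes in each of the 3 water (blue) and 4 DSS (red) libraries, with black bars for group means. Lyz1 and Lyz2 lay lower in all 4 DSS libraries than in all 3 water libraries, while Kit overlapped between the groups.

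No cell cycle gene passed over its list alone. Cycling cells that the sort could have held were not measured apart from Paneth cells. The 45 genes of G2 and M phase had a median log2 change of -0.25 and a camera adjusted p of 5.02e-10, which became adjusted p = 0.688 with an estimated correlation. That median was -0.16 without water 1 and -0.15 without DSS 3. Bub1, a mitotic checkpoint kinase, was at -0.44 ± 0.13 and Mki67 at -0.27 ± 0.15. The 37 S phase genes had a median of -0.02 (camera adjusted p = 0.923). Of 19 tested p53 target and DNA damage genes, Phlda3 and Ccng1 fell by 1.15 and 0.50 on the log2 scale, adjusted over the list alone, and the list's camera adjusted p of 4.56e-05 became adjusted p = 0.245 with an estimated correlation.

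No inflammatory gene list passed camera as higher in DSS. The 37 type I interferon response genes had a median log2 change of -0.14 (camera adjusted p = 0.000167, or adjusted p = 0.297 with an estimated correlation), with Ifi27 at -0.39 ± 0.10, and a median of -0.22 without water 1. The 22 interferon-gamma-induced GTPases and chemokines had a median of -0.27 (adjusted p = 0.0298, or adjusted p = 0.867 with an estimated correlation). Without water 2 the median of these interferon-gamma-induced GTPases and chemokines was 0.06 (adjusted p = 0.857), without water 1 it was -0.57, and they did not pass without DSS 1, with a median of -0.16 (0.399), or without DSS 2 (0.0532). Lists of NF-kB and inflammatory chemokines, inducible mucosal defence genes and MHC class I genes did not pass (camera adjusted p of 0.929, 0.843 and 0.843). Reg3g, an inducible antimicrobial lectin, ranged from 234 to 2605 CPM among DSS libraries and from 592 to 1456 CPM among water libraries. Of 23 receptor components for IL-22, IL-17 and TNF, Il17rc rose by 0.31 ± 0.07, adjusted over the list alone.

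Over all 17449 genes tested, edgeR called 0 as genes higher in DSS and 0 as genes lower in DSS at an adjusted p under 0.05, and the lowest adjusted p was 0.123. At an unadjusted p under 0.05 there were 2742 genes, 15.7% of those tested. DESeq2, run without the low-count filter over 35081 genes, called 346 higher and 296 lower, and limma-voom 0 and 0 over the 17449 genes. edgeR without a low-count filter called 240 and 201, without DSS 1 it called 168 and 135, and without DSS 4 it called 9 and 0. All 4 DSS libraries lay above all 3 water libraries for 1291 genes, 7.40% of those tested, and below for 1311 genes, 7.51%. Chance gives 2.86% in each direction only as an average over all splits of the libraries. The shares were not computed for the other splits, so whether they exceed chance was not tested. The smallest p-values, none past the threshold, were sought with predicted, unnamed, clone and pseudogene symbols left out. They belonged to Aldh1l1, Slc10a2, Rpl23a, Cpm and Camk1d among the higher and Manf, Ero1lb, Colca2, Tmed2 and Phlda3 among the lower. Aldh1l1, a folate enzyme, was at 0.56 ± 0.08, Cpm, a carboxypeptidase, by 0.50 ± 0.07, Camk1d, a kinase, by 0.41 ± 0.07, Ero1lb, an endoplasmic reticulum oxidase, by -0.51 ± 0.08 and Colca2 by -0.54 ± 0.08.

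RNA isolation days each held mice of 1 group, so the day and the group cannot be told apart. Ages were unequal as well, with DSS 1 the only 12-week mouse on DSS, beside water 1 and water 2 on water. Water libraries were all named for lane 6, as was DSS 4, while DSS 1 and DSS 3 were named for lane 8 and DSS 2 was merged. Against the 3 water libraries, DSS 4 alone, as lane 6 only, gave 3 genes higher and 6 lower, with DSS 4 assumed to vary like the water libraries.

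Coordinates follow the count files, which use the mouse build mm10 and GENCODE release 15 gene models, and each value is the sum over a gene's exons. Kit (ENSMUSG00000005672.12) lies on chromosome 5 from 75574916 to 75656722 on the plus strand. Lyz1 (ENSMUSG00000069515.6) lies on chromosome 10 from 117287797 to 117292868 and Lyz2 (ENSMUSG00000069516.8) beside it from 117277331 to 117282321, both on the minus strand. Lgr5 (ENSMUSG00000020140.15) lies on chromosome 10 from 115450311 to 115587780 on the minus strand, and Manf (ENSMUSG00000032575.16) on chromosome 9 from 106838312 to 106891979 on the minus strand.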

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

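Of the tests in this part, the splits for edgeR, the spread among granule genes, the ribosomal excess over all genes with library totals only, the depth comparison, the separate look at DSS 1 to DSS 3 and the repeat over weakly covered receptor genes were chosen after the result was seen. Among the 4 DSS libraries, 10 of 106 series had 1 library far from the others by the gap to the nearest library over the range, past Dixon's 95% limit for 4 samples, which chance passes in about 5% of series. DSS 1 stood apart for MHC class II genes (ratio 0.860, mean log2 level -1.80 against 0.697 to 1.10), Ascl2 (0.909), Rpl23a (0.909), Rpl29 (0.850) and Fam84a (0.852). DSS 4 stood apart for the Notch pathway (0.876), Camk1d (0.869), Fzd5 (0.868) and the genes with a count at equal totals without granule genes (0.850). DSS 2 stood apart for receptor gene counts (0.830).

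Chance cannot be excluded for the count of genes in DESeq2 or of lists in camera. For edgeR the count of splits decides nothing, since any of the 35 splits gives at least the real 0 genes (35 of 35), and the highest of the others gave 206. The 642 genes of DESeq2 were matched or exceeded in 2 of the 35 splits, the other being 1183 when DSS 1 was grouped with the water libraries. That split also gave the 206 genes in edgeR, so by these gene counts DSS 1 lies with water. DSS 1 was the only 12-week mouse on DSS, and water 1 and water 2 were 12 weeks old. That split therefore puts all 12-week mice in the same group, and its counts cannot tell age from the response to DSS. The nearness of DSS 1 to water does not hold for every list. The mean log2 level of the unfolded protein response was -0.32 in DSS 1 and -0.36 in DSS 2, against -0.14 to 0.17 in water. The split that follows the lane, with DSS 4 beside the water libraries, gave 11 genes in edgeR and 101 in DESeq2. For camera, 17 of the 35 splits called as many lists as the real split's 14, and the highest of the others called 21. The number of camera calls with the preset correlation is therefore not evidence for an effect of DSS in these libraries. For the ribosomal list the adjusted p was 4.94e-44 in the real split and smaller only with DSS 1 beside the water libraries (6.21e-57). With DSS 2 there instead it was 2.31e-22, and the weakest split gave 0.877. A camera call of this list alone is thus not evidence either.

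Beside the lower granule genes, the median of the ribosomal protein genes exceeded that of random sets matched on length, GC content and level by 0.306 on the log2 scale. The highest of 10000 sets reached 0.0741. Length and GC content were those of the longest annotated transcript, with a median length of 1077 bases against 1267 in the matched genes. Measured in this way, they do not account for the rise. The transcripts actually expressed were not measured, so a length bias is not excluded. The same matched sets argue against a wrong scaling factor, which moves all genes of a library alike, while leaving granule genes out of the scaling (0.295) and the excess over all genes with library totals only (0.303) moved almost nothing and decide nothing alone. Fewer Paneth cells in the DSS sorts stay undecided. Fewer cells alone would lower all granule genes alike, whereas the log2 differences of 34 abundant granule genes ranged from -1.03 to 0.909. As large a variance of these differences came from 3 of the 35 splits. With so few splits only the largest variance of all could have counted against fewer Paneth cells, so this test cannot decide. In DSS 3 and DSS 4, with granule genes at -0.78 and -0.71, tuft cell markers lay at 0.78 and -0.07, goblet at -0.08 and 0.37, enterocyte at 0.44 and 0.10 and enteroendocrine markers at 0.85 and 1.14, the last against -2.41 to 1.46 in water, which settles nothing in so few libraries. An effect of DSS stays open beside it, as a hypothesis, since each isolation day held libraries of 1 group only.

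More genes had a count in the DSS libraries, 27294 ± 1201 (SD, n = 4) against 24727 ± 441 in water (SD, n = 3). Depth does not account for this, since at equal totals the lowest DSS library still exceeded the highest water library by 499 genes. Fewer reads taken by granule genes may account for DSS 4, which overlapped water once those genes were left out (-111 genes), but not for DSS 1 to DSS 3, which stayed at least 1514 genes higher. Counts over olfactory and vomeronasal receptor genes could not decide on background reads (-23.7 CPM), because the gene Olfr418, named after its value was seen, held 61.3% of them. Over the 1421 receptor genes below the expression filter every DSS library exceeded every water library, by at least 1.21 CPM, and at 15.7, 17.7 and 17.7 in DSS 1 to DSS 3 against 7.70 in DSS 4 this background may go with the lane, while an effect of DSS itself was not tested.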

How the results depend on the processing

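The gene counts moved with the setting. edgeR's 0 genes higher and 0 lower became 2107 and 28 with library totals only, 240 and 201 without a low-count filter and 3 and 6 in lane 6 libraries only, and DESeq2 called 346 and 296. Without each replicate in turn the genes higher in DSS ran from 0 to 168 and the genes lower in DSS from 0 to 135, the highest without DSS 1, with 9 and 0 without DSS 4. Library totals only moved the median of all genes by 0.23 on the log2 scale, so values under that setting are relative to this shift, and 98.7% of its calls were higher against 53.9% for DESeq2. Robust dispersions, age, other size factors, a fold of 1.5, limma-voom, a stricter filter and scaling without granule genes kept both counts at 0. camera called between 12 and 17 gene lists in every setting that refitted the data, and gene list tests gave 0 with an estimated correlation, 0 with the fry direction test and 0 by exact permutation of list means. The permutation could hardly pass, since its smallest p is 0.0286 before adjustment over 34 lists. The estimated correlation gave adjusted p = 0.297 for cytosolic ribosomal proteins, secretory pathway machinery and Paneth antimicrobial and granule genes and adjusted p = 0.245 for the unfolded protein response. fry gave 0.0883 for cytosolic ribosomal proteins, 0.0746 for secretory pathway machinery and the unfolded protein response and 0.161 for Paneth antimicrobial and granule genes, and exact permutation gave 0.243 for each. The mixed test of fry, which asks whether members change in either direction and compares with no other genes, passed for 15 lists, with adjusted p of 0.0322 for the ribosomal and granule lists, 0.0109 for the secretory list and 0.0107 for the unfolded protein response. Leaving out 1 library, with the preset correlation, ended the call for the Notch pathway (without water 2, water 3, DSS 1 or DSS 4), mitochondrially encoded genes (water 1, water 3, DSS 1 or DSS 2), oxidative phosphorylation (DSS 2) and interferon-gamma-induced GTPases (water 2, DSS 1 or DSS 2). It brought a call for MHC class II (water 2 or DSS 1), Wnt targets and Paneth specification (DSS 3), cholesterol synthesis (water 2), enterocyte markers (water 3) and enteroendocrine markers (water 1, water 2, water 3 or DSS 2). With an estimated correlation, chosen after seeing the data, no list passed without any 1 library. The lowest adjusted p was 0.150, for the type I interferon response without water 1. The share of counts in the Paneth antimicrobial and granule genes kept its direction in the 9 settings tried, with the largest fall of -11.4 points without DSS 1. Leaving out 1 library could not have turned this direction, since every DSS library lay below every water library. The setting over alpha-defensins only measured a smaller share, 17.2% in water and 13.4% in DSS, which differed by -3.79 points. The cause of these changes was not tested, apart from fewer samples or genes where a setting removes them. Leaving out DSS 2 with DSS 3, robust dispersions and permuting list means were chosen after seeing the data. Total counts limit genes below 0.129 CPM, the level of 3 counts in the smallest library.

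Directions turned mostly for lists and genes near 0, as median or single log2 changes. With library totals only the value was 0.22 for stem cell genes, 0.22 for cell cycle, S phase, 0.00055 for secretory pathway machinery, 0.10 for type I interferon response, 0.22 for NF-kB and inflammatory chemokines, 0.23 for goblet cell markers, 0.23 for enteroendocrine cell markers, 0.12 for mitochondrially encoded genes, 0.23 for proteasome subunits, 0.20 for cholesterol synthesis, 0.062 for p53 target and DNA damage genes, 0.14 for IL-22, IL-17 and TNF receptor components, 0.0011 for Wnt3, 0.17 for Olfm4 and 0.00065 for Cd24a. With limma-voom the value was 0.0096 for stem cell genes, 0.0017 for cell cycle, S phase, -0.017 for inducible mucosal defence genes, 0.51 for enteroendocrine cell markers and -0.22 for Reg3g. Without a low-count filter the value was 0.0027 for stem cell genes, 0.029 for NF-kB and inflammatory chemokines, 0.00997 for goblet cell markers and 0.00073 for proteasome subunits. With at least 1 CPM in 4 libraries the value was 0.014 for NF-kB and inflammatory chemokines. With age as a covariate the value was 0.054 for stem cell genes, -0.043 for reserve and injury-induced stem cell genes, 0.018 for cell cycle, S phase, -0.037 for MHC class I antigen presentation, -0.12 for MHC class II antigen presentation, -0.037 for enterocyte markers, -0.018 for retinol and bile-acid or xenobiotic metabolism and 0.0045 for Olfm4. In lane 6 libraries only the value was -0.012 for reserve and injury-induced stem cell genes, 0.12 for cell cycle, S phase, -0.0035 for Wnt target genes, -0.17 for inducible mucosal defence genes, 0.15 for goblet cell markers, 0.26 for enteroendocrine cell markers, -0.0801 for tuft cell markers, -0.0045 for enterocyte markers, -0.35 for T, B and other leukocyte markers, -0.039 for endothelial markers, 0.021 for cholesterol synthesis and -1.99 for Reg3g. In 10-week mice only the value was 0.022 for stem cell genes, 0.021 for cell cycle, S phase, 0.072 for interferon-gamma-induced GTPases and chemokines, 0.066 for NF-kB and inflammatory chemokines, 0.10 for goblet cell markers, -0.21 for enterocyte markers and -0.085 for Kitl. Without DSS 2 and DSS 3 the value was 0.067 for stem cell genes, 0.072 for cell cycle, S phase, -0.0031 for MHC class I antigen presentation, -0.21 for inducible mucosal defence genes, 0.0082 for goblet cell markers, 0.022 for enteroendocrine cell markers, -0.051 for tuft cell markers, -0.0205 for enterocyte markers, -0.19 for T, B and other leukocyte markers, -0.0101 for endothelial markers, 0.067 for Olfm4 and -0.94 for Reg3g. Without each replicate in turn the range was -0.011 to 0.066 for Paneth specification and identity, -0.044 to 0.047 for stem cell genes, -0.0799 to 0.047 for cell cycle, S phase, -0.57 to 0.065 for interferon-gamma-induced GTPases and chemokines, -0.028 to 0.12 for MHC class I antigen presentation, -0.046 to 0.0031 for NF-kB and inflammatory chemokines, -0.15 to 0.043 for goblet cell markers, -0.59 to 0.60 for enteroendocrine cell markers, -0.041 to 0.26 for enterocyte markers, -0.087 to 0.10 for cholesterol synthesis, -0.054 to 0.21 for retinol and bile-acid or xenobiotic metabolism, -0.086 to 0.17 for Kitl, -0.13 to 0.019 for Olfm4 and -0.54 to 0.77 for Reg3g.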

Other observations

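Of the values in this part, those without DSS 2 and DSS 3 together, the estimated correlation without single libraries and the region test without Fabp6 were chosen after the result was seen. Markers of other cell types differed between single libraries. The 25 tuft cell markers, genes of the chemosensory cells of the epithelium, had a median log2 change of 0.46 and a camera adjusted p of 6.77e-06, or adjusted p = 0.688 with an estimated correlation, with 0 members past the threshold over the list alone. Their mean log2 level relative to water was 0.75 in DSS 2 and 0.78 in DSS 3, which share an isolation day and, with water 3 at -0.01, a title number, but -0.03 in DSS 1 and -0.07 in DSS 4, and the median of the tuft cell markers was -0.051 without DSS 2 and DSS 3. Pou2f3, the transcription factor of tuft cells, was at 0.72 ± 0.23, Chat at 0.90 ± 0.31 and Plcg2 at 0.62 ± 0.22. The 32 enteroendocrine markers lay at -2.41 in water 1 against 0.94 and 1.46 in water 2 and water 3, and at 0.56, 0.06, 0.85 and 1.14 in DSS 1 to DSS 4 (camera adjusted p = 0.0957). The median of the enteroendocrine cell markers was -0.59 without water 1 and 0.60 without water 3, each past the camera threshold with the preset correlation (adjusted p = 0.635 and adjusted p = 0.676 with an estimated correlation).

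Of 25 goblet cell markers Clca1, a mucus-processing protein, rose from 97.7 ± 20.7 CPM in water (SD, n = 3) to 436 ± 279 CPM in DSS (SD, n = 4), adjusted over the list alone, and the list did not pass (camera adjusted p = 0.464). The endothelial and leukocyte markers, cells the sort removes, did not pass (0.171 and 0.413), nor did the MHC class II genes (0.171), of which Ctss rose by 0.48 ± 0.11, adjusted over the list alone. The median of the MHC class II genes was 0.48, but 1.08 without water 2 and 0.76 without DSS 1. Each of these 2 passed camera with the preset correlation (adjusted p = 0.693 and adjusted p = 0.470 with an estimated correlation). Glycolysis genes had a median of 0.15 (adjusted p = 0.000177, or adjusted p = 0.307 with an estimated correlation), with Gpi1 at 0.33 ± 0.09. Immediate early and dissociation genes had a median of 0.25 (0.000399, or adjusted p = 0.297), and nuclear-encoded oxidative phosphorylation genes 0.068 (0.00357, or adjusted p = 0.688), which did not pass without DSS 2 (0.0612). Notch pathway genes had a median of 0.11 (0.0275, or adjusted p = 0.297) and did not pass without water 2, with a median of 0.072, water 3, DSS 1 or DSS 4 (0.0870, 0.0611, 0.0592 and 0.0508). For mitochondrially encoded genes the sign of the median depended on the scaling, though it lay below the median of all genes under both scalings. Their median was -0.12 (0.0259, or adjusted p = 0.688), but 0.12 with library totals only, where the median of all genes was 0.23. A share of counts was taken over a wider set, all genes with a mitochondrial symbol, so it does not describe the list. That share was 1.93% ± 0.193 in water (SD, n = 3) and 2.17% ± 0.164 in DSS (SD, n = 4), with an exact permutation p of 0.20. The 9 tested genes of the list, all protein-coding, did not pass without water 1, water 3, DSS 1 or DSS 2 (0.279, 0.0988, 0.0647 and 0.0660). Their medians were -0.064 without water 1, -0.071 without water 3 and -0.19 without water 2. Among them mt-Nd3 fell by 0.37 on the log2 scale, adjusted over the list alone. Cholesterol synthesis, retinol and bile-acid or xenobiotic metabolism, proteasome subunits, receptor components and niche signals did not pass (0.413, 0.413, 0.923, 0.925 and 0.679). Median, mean and camera direction differed in sign for 7 lists, among them goblet and enteroendocrine markers.

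Of 35 enterocyte markers, Slc10a2, the ileal bile acid transporter, rose by 1.73 ± 0.24 from a low 0.422 ± 0.111 CPM, Enpep rose by 1.18 ± 0.28 and Mgam by 0.33 ± 0.08, while Ada, high in the duodenum, fell by 0.62 on the log2 scale, adjusted over the list alone. The enterocyte markers did not pass (camera adjusted p = 0.192) but did without water 3 (0.00677, or adjusted p = 0.676 with an estimated correlation). A candidate explanation is that the DSS crypts came from a more distal stretch of the small intestine. A second set of 7 distal and 7 proximal genes, fixed before this test was run, differed in that direction by 0.42 on the log2 scale, but an exact permutation test gave p = 0.20 over the 35 splits, 0.236 when adjusted. The set shares Fabp6 with the enterocyte markers, and without it 6 distal and 7 proximal genes differed by 0.45 (exact permutation p = 0.114), so this stays undecided.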
